A study of Caenorhabditis elegans with 4 samples.

How the data were processed

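HDA-1 was profiled by ChIP-seq in N2 larvae at the L3 stage, in 2 ChIP libraries with 2 input libraries. Per the labels' protocols, frozen and ground worms were crosslinked for 20 minutes in EGS, a long-arm protein crosslinker, and for 10 minutes more with formaldehyde added. The chromatin was sonicated and precipitated with antibody and magnetic beads. Fragments were ligated to Illumina adaptors, amplified by PCR, selected by size on a gel and sequenced on a GAII or HiSeq2000. EGS joins proteins that do not touch DNA themselves, so a peak can mark a site that HDA-1 reaches through other proteins.

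Per the submitters' processing notes, BWA and the ce10 build were used. Per the file headers, the coordinates are on the WormBase WS220 build and the peaks were called with MACS. The version of MACS, its threshold, its control library and any filter are not given in the sources used here. Each ChIP replicate has its own peak list, and the list of the whole series names no replicate. The deposited values are a position and a score for each peak, and the score is the authors' own. What the score measures is not stated, so strong and weak peaks below mean peaks high and low in score, not in measured binding. It begins at 1.30 in both replicate lists and 1.31 in the whole-series list, and 1.30 is −log10 of 0.05. The score was used to describe, rank or filter peaks within a list, and its agreement between the replicates was described across 5927 matching pairs. For the tests of hypotheses, each matching peak was ranked within its own list over those pairs alone. A ratio of the scores had been tried first, with the same direction of the arm difference, and was replaced because scores of separate lists need not share a scale. The input libraries were not analysed here, so no background level was measured beside the peaks.

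The lists hold no read counts, so no depth or floor can be given for a site. A list from a deeper or cleaner library would be longer at the same threshold, and list length was therefore checked with lists of equal number. Chromosome spans were taken as the largest peak end over the 3 lists, since no genome of this build was used here. They sum to 100.2 Mb. Peaks were counted on 6 nuclear chromosomes.

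Peaks were called shared where they overlapped by at least 1 bp. The overlap was set against 1000 random circular shifts of the other list within each chromosome, which keep the widths and spacing of its peaks. Matching pairs for rank agreement were peaks that were each other's largest overlap. Peak density on X was compared with the autosomes by an exact binomial test against the share of the span. Arms against centre were compared over the 5 autosomes by an exact sign-flip permutation test of log2 density ratios. Shares of peaks were compared by Fisher's exact test. Genomic units (peaks, bins or chromosomes) and not samples are the units of these tests, so the p-values say nothing of the spread between cultures. Clustering was compared with 100 random placements.

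The named peaks were set by a rule: the 10 best-scoring whole-series peaks that overlap both replicates, and the 5 windows of 20 kb with the most peaks. The tests of overlap, rank agreement, whole-series support, X against autosomes, arms against centre, and width and spacing, with their alternatives, were fixed before the data were examined. The positions of the longest gaps, the densest and sparsest bins and the widest peaks were chosen after their values were seen. The comparison of V with the other autosomes, the differences between replicates, the strongest 10%, the 1-Mb bins and the random placements for clustering were added afterwards. Alternatives tried were an overlap of at least 50% of the shorter peak, midpoints within 100 bp, the better-scoring 50% of each list, random placement, each replicate alone, arms and centre of 33.3% of the length, the strongest 20% in place of 10%, the 5000 best-scoring peaks of each replicate, and merging of peaks closer than 1 kb. The code was checked on simulated lists. In the first, 60.0% of the 11762 replicate 1 peaks were kept with small moves and the rest were scattered away from them. The overlap function returned 60.0%, as working code has to under this design. In the second, uniform positions not drawn from the peaks gave an arm-to-centre log2 ratio of 0.49 where 0.5 had been set. These checks cover the code only and say nothing of how the tests behave on clustered peaks.

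Planned comparisons with gene starts, with 21 gene lists and with sequence motifs were not run, because the gene table at hand is of another build and coordinates of different builds were not mixed. Peaks are therefore named by position alone. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.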

Results

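Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genomic binding sites of HDA-1 in Caenorhabditis elegans. HDA-1 is a class I histone deacetylase of this nematode, an enzyme that removes acetyl groups from histones and works in corepressor complexes such as NuRD. Wild-type N2 worms, the standard laboratory strain, were grown at 20 °C and collected as L3 larvae from a mixed population of males and hermaphrodites. The antibody was an affinity-purified rabbit polyclonal raised against HDA-1. The series holds 2 HDA-1 ChIP libraries (replicates 1 and 2) and 2 input DNA libraries. The values are peak lists, 1 for each ChIP replicate and 1 for the whole series, on the WS220 (ce10) build. Replicate 1 held 11762 peaks, replicate 2 held 9901 and the whole-series list held 14199. The peaks covered 3.89 Mb in replicate 1, 2.73 Mb in replicate 2 and 4.66 Mb in the whole-series list, the last being 4.65% of the 100.2 Mb spanned. The lists carry no read counts, so the sequencing depth behind a peak is unknown. With 2 replicates, both values are given side by side. Nothing in the labels says whether the replicates came from separate cultures. Confidence intervals below are exact 95% intervals that cover counting error only and treat peaks as independent.

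The first comparison asked how far the replicates placed HDA-1 at the same sites. Of the replicate 1 peaks, 6054 (51.5%, interval 50.6 to 52.4%) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 6459 (65.2%, interval 64.3 to 66.2%) overlapped a replicate 1 peak. High-scoring sites recurred far more often than low-scoring ones. In the best-scoring 25% of replicate 1, 88.1% of peaks were found in replicate 2, against 26.6% in its lowest-scoring 25%. The same shares for replicate 2 were 93.5% and 47%. On chromosome X, 44.3% of the replicate 1 peaks (interval 42.2 to 46.3%) recurred in replicate 2, against 50.8% to 55.5% on the autosomes. In the other direction the X share was 68.4%, with 61.2% to 67.1% on the autosomes. Replicate 1 had 2287 peaks on X and replicate 2 had 1583, and such unequal counts alone pull the 2 X shares apart.

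These overlaps exceeded what the spacing of the peaks gives by position alone. After 1000 circular shifts of the other list along each chromosome, a mean of 5.76% of replicate 1 peaks and 6.95% of replicate 2 peaks overlapped. The highest shifted values were 7.37% and 8.48%, so both one-sided permutation p-values were 0.001, the smallest that 1000 shifts can give. The shifts keep the spacing of the peaks but not the sequence under them, and the inputs were not analysed. The excess therefore cannot tell shared HDA-1 sites from background common to both libraries. Peak scores agreed only in part. Across 5927 pairs of matching peaks, which are not independent replicates, the scores correlated with a Spearman rho of 0.52 and a Pearson r of 0.53 on the log10 scale. Of the 1000 best-scoring replicate 1 peaks, 966 overlapped some replicate 2 peak, and 497 overlapped one of the 1000 best-scoring there.

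The whole-series list was then compared with the replicate lists. Among its 14199 peaks, 5947 (41.9%, interval 41.1 to 42.7%) overlapped a peak in both replicates. A further 4109 (28.9%) overlapped replicate 1 only, 2549 (18%) replicate 2 only, and 1594 (11.2%) neither. Sites found in both replicates had a median score of 19.5 and a median width of 386 bp. Sites found in neither had a median score of 4.64 and a median width of 165 bp. Of the best-scoring 10% of these peaks 98.7% were found in both replicates, and of the lowest-scoring 10%, 2.82% were. The whole-series list lacked 1678 replicate 1 peaks, with a median score of 4.40, and 802 replicate 2 peaks, with a median score of 5.46. Only 1 peak of each replicate was missing from it while overlapping the other replicate. How the whole-series list was made is not given in the sources used here, and it is not independent of the replicate lists.

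**Figure D1:**
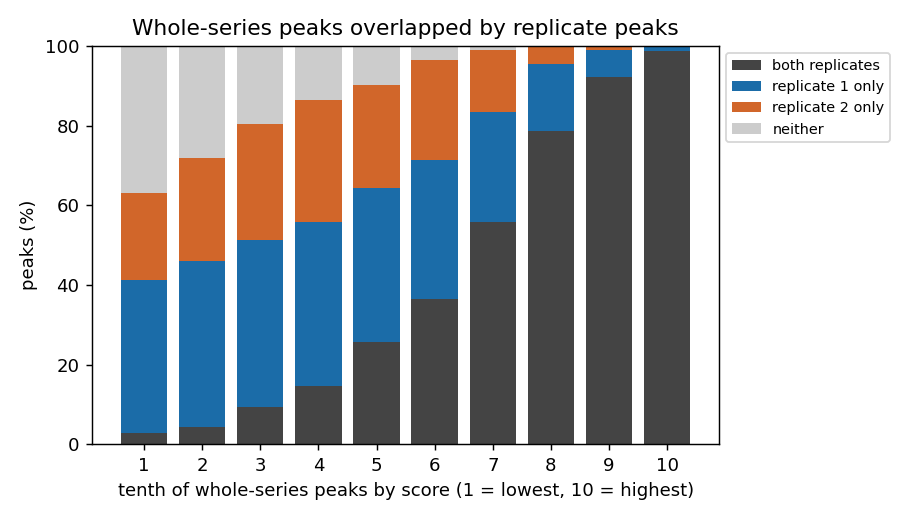
Share of whole-series peaks (y axis, percent) that overlapped a peak in both replicates, in 1 replicate or in neither, in 10 groups of rising whole-series score (x axis, 1 lowest to 10 highest, about 1420 peaks each). The share found in both replicates runs from 2.82% in the lowest group to 98.7% in the highest.

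HDA-1 peaks were unevenly spread over the chromosomes. Chromosome V, which carries large families of chemoreceptor genes, had the lowest density in each list, with 85.6 peaks per Mb in replicate 1, 76.5 in replicate 2 and 106 in the whole-series list. The other autosomes together had 125, 109 and 151 peaks per Mb. The ratio of V to the other autosomes was 0.69 in replicate 1, 0.70 in replicate 2 and 0.70 in the whole-series list, where an exact two-sided binomial test gave p = 2.13e-53. This comparison was added after the data were examined, and the test treats clustered peaks as independent, so the p-value overstates the evidence. After peaks closer than 1 kb were merged, the whole-series log2 ratio was -0.415 (p = 1.85e-24 by the same exact test), against -0.506 before. Chromosome III was the densest in each list, with 138, 124 and 169 peaks per Mb. Chromosome IV had the next lowest density after V in each list, with 102, 88.8 and 123 peaks per Mb. Replicate 2 had 89.4 peaks per Mb on X, with a counting interval of 85.0 to 93.9 that includes its value on IV.

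The X chromosome, the target of dosage compensation in hermaphrodites, differed between the replicates. In replicate 1 it had 129 peaks per Mb against 115 on the autosomes, a ratio of 1.12 (exact two-sided binomial test, p = 6.32e-07). In replicate 2 it had 89.4 against 101, a ratio of 0.89 (p = 9.53e-06 by the same exact test). X held 19.4% of the peaks in replicate 1 and 16% in replicate 2, a difference of 3.46 percentage points (Fisher's exact test, two-sided p = 3.44e-11). After peaks closer than 1 kb were merged, the difference was 2.06 points (Fisher's exact test, two-sided p = 0.00115). The whole-series list had 150 peaks per Mb on X and 140 on the autosomes, a ratio of 1.07 (exact binomial p = 0.00132). This ratio fell below 1 in its better-scoring 50%, with a log2 value of -0.060 (exact binomial p = 0.191). An excess or a deficit of HDA-1 peaks on X therefore did not hold across the 2 replicates. These tests treat peaks as independent, although neighbouring peaks are clustered. Fisher's test also treats the 2 lists as separate samples, although 6054 replicate 1 peaks and 6459 replicate 2 peaks overlap the other list. Its p-value is therefore not exact for this comparison.

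**Figure D2:**
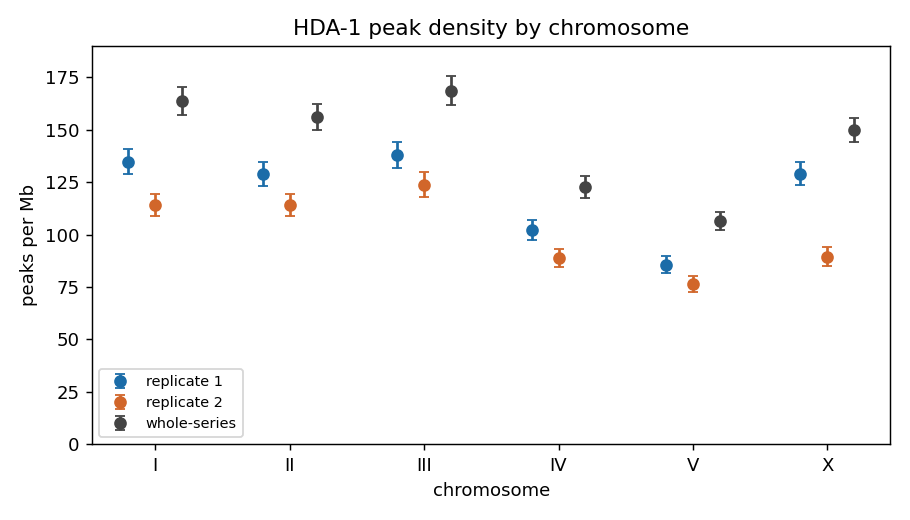
Peaks per Mb (y axis) on each chromosome (x axis) in replicate 1, replicate 2 and the whole-series list, with 95% Poisson counting intervals as bars. Chromosome V is lowest in each list, at 85.6, 76.5 and 106 peaks per Mb, and X had 129 in replicate 1 and 89.4 in replicate 2.

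Along the chromosomes, the replicates differed in how HDA-1 peaks were divided between arms and centres. In C. elegans the autosome centres are rich in conserved genes and the arms are rich in repeats and heterochromatin. Arms were taken as the outer 25% at each end and the centre as the middle 50%. In replicate 1 the arms of the 5 autosomes were less dense than the centres, with a mean log2 ratio of -0.46 ± 0.26 (SD over 5 autosomes) and all 5 below 0. The exact sign-flip permutation test gave a two-sided p of 0.0625, the smallest that 5 autosomes allow. In replicate 2 the mean was 0.094 ± 0.17, with 1 of 5 below 0 (exact permutation p = 0.3125). In the whole-series list it was -0.15 ± 0.20, with 4 of 5 below 0 (exact permutation p = 0.125). Chromosome V had the lowest ratio in each list, at -0.87, -0.20 and -0.50.

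The difference between the replicates had the same sign on every chromosome. The log2 ratio was higher in replicate 2 than in replicate 1 by 0.52 ± 0.15 (SD over 6 chromosomes, X included), with a range of 0.37 to 0.69 (exact sign-flip permutation, two-sided p = 0.03125, the smallest that 6 chromosomes allow). Over the 5 autosomes alone, the unit of the planned arm test, the exact permutation p was 0.0625, which does not pass 0.05 and is the smallest that 5 allow. The test of this difference was added after the data were examined. All 6 chromosomes come from the same 2 ChIP libraries, so they are not replicates of the difference between those libraries. Shared peaks are the same sites in both lists, so a difference between the lists has to fall on the peaks that are not shared. In replicate 2 the 3442 such peaks had a mean log2 ratio of 1.11 ± 0.21 (SD over 5 autosomes) and the 6459 shared peaks a ratio of -0.45 ± 0.31. In replicate 1 the shared peaks had a ratio of -0.41 ± 0.31 and the 5708 others one of -0.51 ± 0.24. Of the autosomal whole-series peaks found in replicate 2 only, 67.8% (interval 65.7 to 69.7%) lay in the arms, against 53.4% (50.6 to 56.1%) of those found in neither, 43% of those found in both and 38.8% of those found in replicate 1 only.

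**Figure D3:**
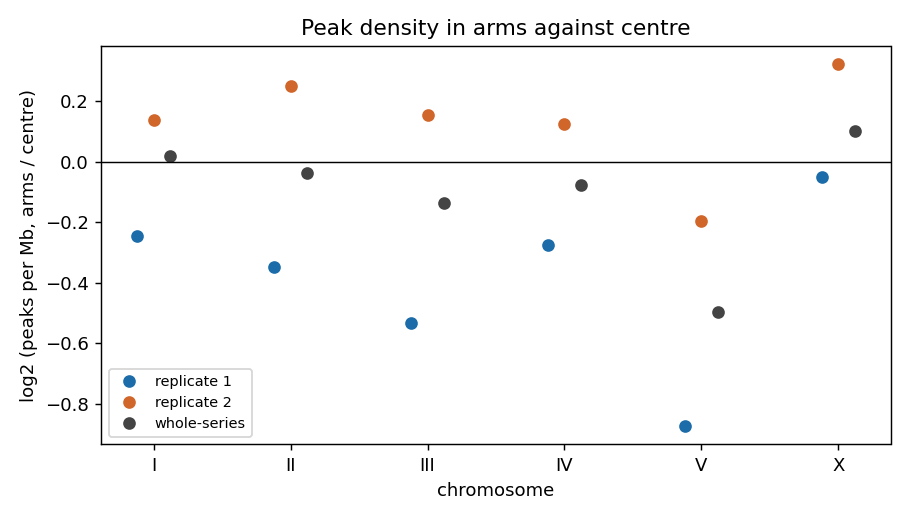
Log2 ratio of peaks per Mb in the arms (outer 25% at each end) to the centre (y axis) for each chromosome (x axis) in replicate 1, replicate 2 and the whole-series list, 1 point per list. The replicate 2 point lies above the replicate 1 point on each of the 6 chromosomes, by 0.37 to 0.69.

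**Figure D4:**
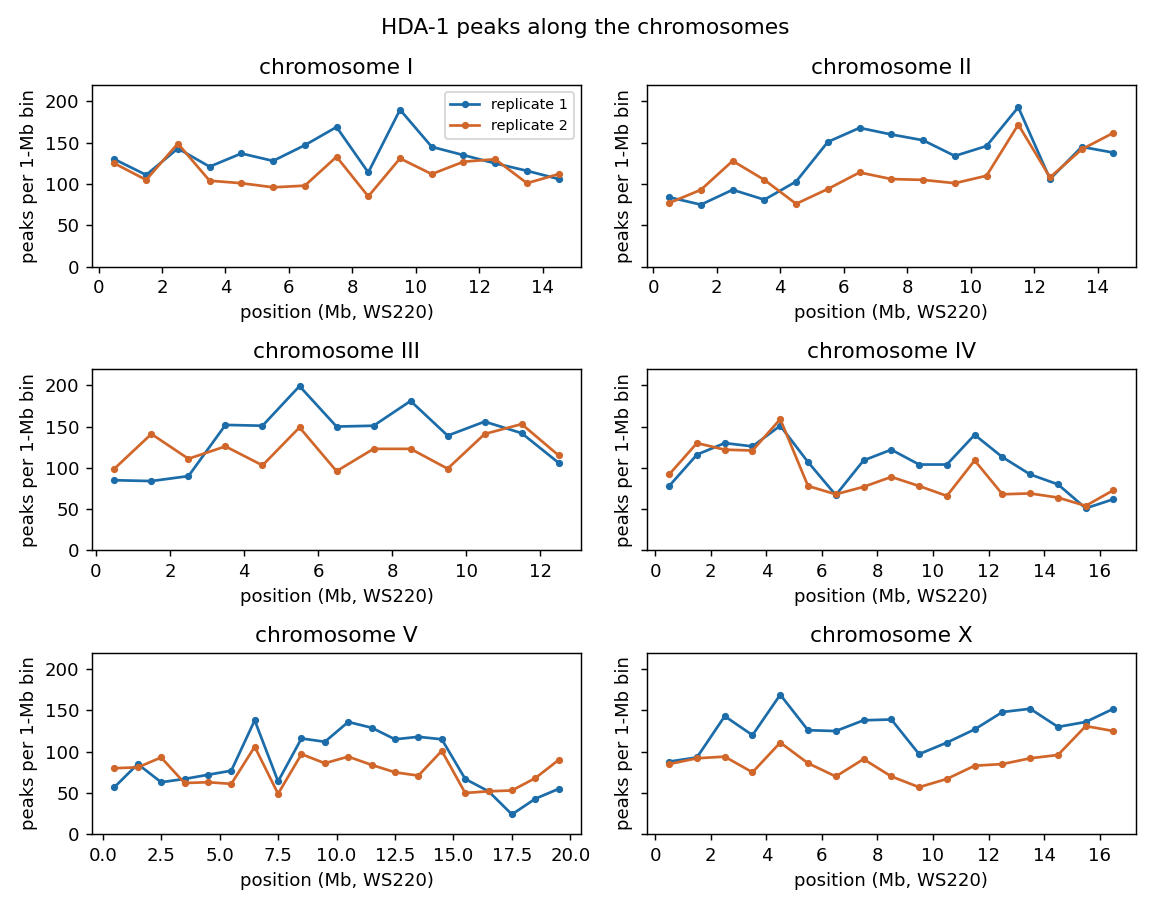
Number of peaks per 1-Mb bin (y axis) along each chromosome (x axis, Mb, WS220 build) in replicate 1 and replicate 2. Replicate 1 had more peaks than replicate 2 in the middle 50% of each of the 6 chromosomes.

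In bins of 1 Mb the peak numbers of the replicates correlated across 97 bins, which are not independent replicates, with a Spearman rho of 0.65 and a Pearson r of 0.65. The densest bin of the whole-series list was chromosome II from 11000001 to 12000000, with 227 peaks (193 in replicate 1 and 172 in replicate 2). It was followed by chromosome III from 5000001 to 6000000 with 213 peaks and III from 10000001 to 11000000 with 204. The sparsest were on the right arm of chromosome V. The bin from 17000001 to 18000000 held 51 peaks (24 and 53 in the replicates), that from 16000001 to 17000000 held 60, and that from 18000001 to 19000000 held 65. The median bin held 148.

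Of the 10 strongest HDA-1 sites found in both replicates, 6 lay on chromosome IV. Those 10 were chosen as the best-scoring whole-series peaks that overlapped both replicates. On IV they lay at 1067321 to 1068224, 3313329 to 3313704, 4720524 to 4720983, 9196140 to 9197502, 15530480 to 15530877 and 16845352 to 16845788. The peak at 9196140 to 9197502 was 1363 bp wide and ranked 1 in replicate 1 (score 140) and 3 in replicate 2 (score 113). The peak at 16845352 to 16845788 ranked 9 and 2. The other strong sites were I at 2639665 to 2639989 (ranks 3 and 6), I at 22217 to 22535 (ranks 7 and 59), II at 4047647 to 4048303 (ranks 3 and 9), and V at 15589934 to 15590567 (ranks 12 and 35). No peak of X or III was among these 10. Their whole-series scores ran from 86.9 to 87.7, with 6 tied at the highest value, so the order of those 6 within that list is not defined. The genes at these positions were not analysed here.

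X was less frequent among the strongest whole-series peaks, but the call depended on how many peaks were taken, and replicate 2 did not share the direction. Among the strongest 10% no chromosome passed the test. Over 18 Fisher's exact tests (6 chromosomes in 3 lists), the lowest Benjamini-Hochberg adjusted p was 0.24. X held 233 of the 1420 strongest whole-series peaks (16%, interval 14.5 to 18.4%) and 19% of the rest, an odds ratio of 0.84 (unadjusted exact p = 0.0197, adjusted p = 0.24). The odds ratio for X was 0.83 in replicate 1 and 1.18 in replicate 2, so its direction differed between them. Among the strongest 20%, X passed in the whole-series list, with 461 of the 2840 strongest (interval 14.9 to 17.6%) against 19.3% of the rest (odds ratio 0.81, adjusted p = 0.00266 over 18 exact tests). It also passed in replicate 1 (odds ratio 0.83, adjusted exact p = 0.0164) but not in replicate 2 (odds ratio 1.04, adjusted exact p = 0.698). No other chromosome passed at 20%. Chromosome IV held 15.8% of the strongest 10% and 15% of the rest (adjusted p = 0.65 by the same exact test). Of the 1187 autosomal peaks among the strongest 10% of the whole-series list 43.4% lay in the arms, against 48.1% of the other autosomal peaks (Fisher's exact test, two-sided p = 0.00238). The odds ratio was 0.83 in that list, 0.85 in replicate 1 (exact p = 0.0166) and 0.88 in replicate 2 (exact p = 0.0889). The p-values of these arm comparisons were not adjusted over the lists, and the comparisons were added after the data were examined. They pool peaks of all autosomes as independent units, although peaks are clustered and the planned arm test took each autosome as a unit. The p-values therefore overstate the evidence, and the odds ratios are best read as descriptions.

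HDA-1 peaks were narrow and came in groups. The median width was 258 bp in replicate 1, 218 bp in replicate 2 and 249 bp in the whole-series list, and the narrowest peak was 146 bp in each list. The median distance to the next peak was 2752 bp, 3703 bp and 2263 bp. In the whole-series list 35.4% of these distances were under 1 kb, against a mean of 17.5% and a highest value of 18.1% over 100 random placements of the same peaks. The shares in the replicates were 33.0% and 28.7%, against random means of 14.8% and 12.2%. Close spacing can partly come from a site called in pieces. The wide whole-series peak on I from 7656932 to 7659656 overlapped 1 replicate 1 peak and 5 replicate 2 peaks. The tightest group was on chromosome II from 6820402 to 6840401, where 20 kb held 25 whole-series peaks (18 in replicate 1 and 19 in replicate 2). The next were II from 11719517 to 11739516 with 23 peaks, III from 1920938 to 1940937 with 22, X from 12167738 to 12187737 with 22, and I from 526234 to 546233 with 21. The group on III held 9 replicate 1 peaks and 20 replicate 2 peaks, and that on I held 17 and 10.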

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

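Alternatives for the replicate differences in arm-to-centre ratio and X share, for V, for the strongest 10% and for the share of gaps under 1 kb were chosen after the data were examined, and the others were planned. Of 40 alternative values, 29 kept their direction and side of the threshold or moved by less than the spread, 6 moved by more, 1 newly passed and 4 reversed. Overlap of the replicates exceeded its position-only level under every definition tried, but its size depended on the definition. With midpoints within 100 bp it was 38.9% of replicate 1 peaks and 46.2% of replicate 2 peaks, against 51.5% and 65.2% as reported. Midpoints within 100 bp lowered the share of whole-series peaks found in both replicates to 31.1%, and the better-scoring 50% of each list raised it to 44.5%. That same choice gave a rank agreement of 0.44, a median width of 342 bp, a median gap of 6056 bp and, for X against the autosomes, a reversed log2 ratio of -0.060. With each replicate alone, the log2 ratio of X to the autosomes ranged from -0.17 (replicate 2) to 0.17 (replicate 1). The arm-to-centre log2 ratio ranged from -0.46 (replicate 1) to 0.094 (replicate 2). The log2 odds ratio of X in the strongest 10% ranged from -0.26 (replicate 1) to 0.24 (replicate 2), and the share of gaps under 1 kb from 28.7% to 33.0%. Among the strongest 20% the log2 odds ratio of X was -0.31 and passed the threshold, and the cause was not tested. The direction of the X, arm and strongest-X results thus rests on which replicate is used, and the cause was not tested by these alternatives. V stayed sparser in each replicate and after merging. No paired analysis was possible because the input libraries that share replicate numbers with the ChIP libraries were not analysed here. Gene-start, gene-list and motif alternatives were not run, since they need an annotation or genome of the same build. Unknown depth limits each list: a site missing from a list may lie under its threshold rather than be unbound, as 26.6% of the weakest 25% of replicate 1 peaks recurred against 51.5% of all.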

Other observations

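All tests in this part were chosen after the data were examined. Long stretches without a HDA-1 peak lay mostly on chromosome V. Of the 10 longest gaps in the whole-series list, 8 were on V, 1 on I and 1 on III. The longest ran from 7248126 to 7432475 on V, 184 kb with no peak in either replicate. Over 100 random placements of the same peaks, the longest gap on V was 76.8 kb on average and 119.3 kb at most. Over all chromosomes it was 80.7 kb on average and again 119.3 kb at most. The listed gaps on III (133 kb) and I (130 kb) exceeded that too. Random placement breaks up the groups of peaks, so longer gaps are expected in the real list on any chromosome. V was also the sparsest chromosome, so this comparison shows nothing particular to V. Another 3 gaps on V, from 8669051 to 8773871, from 3927838 to 4029081 and from 8975472 to 9075811, were also empty in both replicates. What lies there, and how well reads map there, was not analysed here.

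Wider peaks tended to score higher, with a Spearman rho of width and score across whole-series peaks, which are not independent replicates, of 0.588 (0.603 and 0.509 in the replicates). A few wide peaks were exceptions. The broadest whole-series peak, on V from 723826 to 727838 (4013 bp), scored 42.99. The next 3, on V from 14741555 to 14745192 (3638 bp), on I from 3389952 to 3393353 (3402 bp) and on II from 3466218 to 3469552 (3335 bp), scored 3.30, 6.86 and 2.56, all below the median of 9.25. Of the 6 next widest, 5 scored from 28.61 to 46.66, and the other, on II from 11214033 to 11216613 (2581 bp), scored 7.72. In the replicates the best peaks overlapping these 4 exceptions scored from 2.57 to 17.75, and 6 of the 8 scores were above the median of their own list. In each replicate they were still below those of the other widest peaks. The latter scored from 37.27 to 69.71 in replicate 1 and from 15.19 to 56.84 in replicate 2. The exceptions were picked by their whole-series score, and that list is not independent of the replicates. The widths are those of the whole-series peaks, and widths in the replicates were not compared. The replicate scores are therefore no separate evidence of a low score for the width. Chromosome IV held 23 of the 100 best-scoring whole-series peaks (exact interval of the share 15.2 to 32.5%), against 15.1% of all peaks, and 21 (interval 13.5 to 30.3%) and 24 (interval 16 to 33.6%) of the best 100 in the replicates. These counts were made only after the top 10 had been seen, and the replicate 1 interval includes the 15.2% of all its peaks. Among the best 500, IV held 17.8% (interval 14.5 to 21.4%) in the whole-series list and 17.4% (14.2 to 21%) in replicate 2, but 14% (11.1 to 17.4%) in replicate 1, where it was below the share of all peaks.

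The higher arm-to-centre ratio of replicate 2 stands out most. A shorter list alone does not account for it: with the 5000 best-scoring peaks of each replicate the difference in log2 arm-to-centre ratio was 0.61 ± 0.18 (SD over 6 chromosomes), above 0 on 6 of 6, against 0.52 in the full lists. A tilt of signal between arms and centres across the whole library is 1 possible source. At matching peaks, the median change in percentile rank (replicate 2 minus replicate 1) was higher in arms than in centres by 6.82 ± 3.66 points (SD, 6 of 6 chromosomes, exact sign-flip permutation p = 0.03125; the 5 autosomes alone cannot go below 0.0625). The difference thus extends to the scores of shared sites. Here too the chromosomes come from the same 2 ChIP libraries and are not replicates. Any cause of stronger arm signal in replicate 2, a true difference in binding included, would give this sign, so the shift cannot single out a library tilt. The control library, fragment recovery and differences between the worm populations remain open as origins of such a tilt, and no biological explanation was tested.

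The larger X share in replicate 1 is less settled. With the 5000 best-scoring peaks of each replicate, X held 17.2% in replicate 1 and 15.2% in replicate 2, a difference of 2.06 points (95% interval 0.616 to 3.50), against 3.46 in the full lists. Merging peaks closer than 1 kb in the full lists lowered the difference to 2.06 points as well. The interval treats the 2 lists as independent, although many of their sites are shared. List length cannot be told apart from other causes of much of this difference, since the interval reaches below 1.73 points, which is 50% of the full value. A different amount of X chromatin, such as another share of males might bring, would lower the rank of X sites in replicate 2 relative to every autosome. The median change on X was 0.202 percentile points (bootstrap 95% interval -1.60 to 1.79), the autosome medians ran from -0.628 to 0.650, and the width of that interval keeps this explanation open too.

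Replicate 1 alone had a peak that began at the first base of a chromosome, and it had one on 6 of 6 chromosomes. Their scores ran from 2.71 to 22.2, and none overlapped a peak of replicate 2 or of the whole-series list. Weak signal is an unlikely cause for the 4 that scored above the list median (I, II, V and X): of the 200 other replicate 1 peaks nearest in score to each, 3.62% on average and 6% at most were missing from the whole-series list. For the 2 below it (III and IV) the average was 39%, so a weak signal missed by chance stays open there. Toward the opposite chromosome end, 5 replicate 1 peaks reached the largest peak end over all lists, with scores from 6.06 to 9.95. None of these overlapped a peak of replicate 2 or of the whole-series list. They set the span of their chromosomes and were not compared with peaks of like score. Chromosome lengths of the build were not used here, so whether each of them lies at the true end is unknown. C. elegans chromosomes end in telomere repeats, to which reads cannot be placed uniquely. For peaks at a chromosome end, a mapping or control difference between the libraries is therefore a candidate explanation beside HDA-1 at telomeres. Neither was tested.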
